A study of Mus musculus with 9 samples.

How the data were processed

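RNA sequencing gave 9 libraries of chondrocytes, the cells of cartilage, isolated with collagenase from the knee joints of wild-type mice and grown in culture, per the labels' protocols. The labels put 3 libraries into each of 3 groups. These are untreated control cells, cells stimulated with interleukin-1β (IL-1β), a cytokine widely used to provoke an inflammatory and catabolic state in cartilage cells, and cells given IL-1β together with recombinant secreted frizzled-related protein 5 (SFRP5), a secreted protein that binds Wnt ligands. The labels give neither the dose nor the length of treatment. No group received SFRP5 alone, so an effect of SFRP5 independent of IL-1β cannot be told from one on the IL-1β response. Nothing in the labels says whether libraries with the same number, or libraries of 1 group, came from separate animals or separate cultures, so p-values here measure the spread between these libraries, which may be technical.

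The values are gene counts as deposited, 1 table for all 9 libraries, with whole numbers that are not scaled between libraries. Per the labels' protocols, RNA was extracted with TRIzol and a column kit, libraries were made with the NEBNext Ultra II Directional kit, and 150 bp paired-end reads were trimmed with fastp, aligned with STAR to mouse mm10 and quantified with RSEM; the submitters' processing notes name the same tools and no versions. RSEM divides reads that match several genes among them and gives estimates that need not be whole, whereas the deposited counts were whole numbers, and how they were rounded is not given in the sources used here. The kit keeps the strand of the RNA, but the strand setting of the counting is not given in the sources used here. The gene positions in the table were compared with a GENCODE M21 annotation of the same mouse assembly: of 52125 gene IDs found in both, 1524 had the same start and end. The positions in the table are thus not those of this annotation, and which release they come from is not given in the sources used here. They may also be on another assembly than the stated mm10, which was not tested. No coordinates are printed. Gene symbols are those the table pairs with its Ensembl gene IDs. Columns were matched to samples by the letter and number in their names; the table's names for the libraries with SFRP5 also hold a number that the labels do not explain.

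The total count per library ranged from 15795985 to 20688963. Of 56748 genes in the table, 29182 had no count in any library, and 15502 passed edgeR's filterByExpr by group and were tested. All numbers of changed genes come from edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, 1 mean per group and 1 fit over all 9 libraries, so that the 3 groups share their estimate of the spread. Each comparison was adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Unless another test is named, every adjusted p of a gene is from this test. Levels are CPM, counts relative to the library size after correction by the TMM factors, as the mean ± SD of 3 libraries. Log2 fold changes carry a standard error (SE) derived from the change and the F statistic of its test. This SE is too small where a change is very large and 1 group is low. The common biological coefficient of variation was 4.97%. A fold against a group with 0 counts is a lower bound computed with 3 counts over the group in place of 0; where a group held 1 to 3 counts, the ratio of depth-scaled counts is given with its exact 95% interval. Such bounds and intervals cover counting error only, as reads from amplified libraries are not independent molecules. The log2 CPM of single libraries used a prior count of 2. They served for correlations between libraries, principal components, the comparison of replicate numbers and the tests of lists.

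Lists of genes were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01 between genes, 1 test per list and comparison, adjusted over the lists of a comparison; a list needed 3 tested members. There were 33 lists. They covered cartilage matrix and chondrocyte identity, glycosaminoglycan synthesis, matrix-degrading proteases, protease inhibitors, inflammatory cytokines and chemokines, NF-κB feedback and target genes, the prostaglandin and nitric oxide pathway, acute phase and complement, Wnt ligands and receptors, secreted Wnt antagonists, Wnt/β-catenin target genes, interferon-stimulated genes, chondrocyte hypertrophy and mineralization, fibroblast-type collagens and dedifferentiation, the cell cycle, cholesterol synthesis and uptake, glycolysis and hypoxia, the unfolded protein and amino acid stress response, antioxidant and NRF2 target genes, the TGF-β and BMP pathway, p53 targets with senescence and apoptosis, immediate early and heat shock genes, and mitochondrially encoded transcripts. The others were markers of macrophages, osteoclasts, neutrophils, lymphocytes, endothelium, skeletal muscle, adipocytes, erythroid cells, osteoblasts and osteocytes, and synovial fibroblasts. Of 603 list entries, 3 were found under another symbol.

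The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 genes with the largest change in each direction of each comparison, among called genes with a mean of at least 5 CPM in the higher group and no overlap between the 3 libraries of each group, passing over clone and model names; 19 genes of interest whatever their values; up to 4 members of each list with the smallest p; for the reversal, the 10 genes called in both comparisons in opposite directions with the smallest larger p; and markers of other cell types. Some genes that the rule or the lists take are not reported here. Any gene or family outside this rule is said to have been picked after its values were seen. Alternatives were RLE or upper-quartile factors, DESeq2 1.42.0, no low-count filter, only the libraries compared, robust dispersions, a fold of at least 2, the replicate number as a block, and each library left out in turn; for lists also camera with an estimated correlation and fry. The comparisons with and without SFRP5 share the IL-1β libraries, so chance values of their overlap were simulated 20 times with no SFRP5 effect.

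The gene test was tested on simulated counts with the real means and library sizes. Of 50 genes changed 2-fold it found 86% for IL-1β against control (15126 genes in the fit), 82% for SFRP5 added to IL-1β (15217 genes) and 84% for both against control (15223 genes); of genes changed 1.5-fold it found 56%, 66% and 78%. Calls among unchanged genes made up 5.19%, 7.80% and 5.30%. Python 3.11.15 served to find genes whose reads could be split with near-identical copies. The 100-base windows of each gene's longest annotated transcript were looked for in all transcripts of other genes. Of 15292 genes 1115 shared over 20% of their windows, and named genes among them are given as uncertain.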

Results

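Gene expression was measured by RNA sequencing in mouse knee chondrocytes kept as control cultures, stimulated with IL-1β, or given IL-1β together with recombinant SFRP5, with 3 libraries in each group. The series is about the production of SFRP5 in cartilage and protection of chondrocytes, so 3 comparisons followed from the design: IL-1β against control, IL-1β with SFRP5 against IL-1β alone, and IL-1β with SFRP5 against control. The total count per library was 17960438 to 20107339 in the control group, 17833535 to 18717286 in the IL-1β group and 15795985 to 20688963 in the group with SFRP5. At these depths 3 counts in 1 library equalled 0.135 to 0.195 CPM. Across genes, which are not independent replicates, the log2 levels of 2 libraries of the same group correlated with r of 0.989 to 0.992, and those of libraries of different groups with r of 0.803 to 0.982. The first principal component held 88.3% of the variance and the second 4.33%. No pair of libraries within a group differed by as little as sampling noise, with a chi-square of 2.22 to 4.99 per gene, where sampling alone gives about 1. The 10 most abundant genes took 19.3 to 19.6% of the counts in control libraries, 15.3 to 15.6% with IL-1β and 14.6 to 15% with IL-1β and SFRP5. Levels in the text are CPM as mean ± SD of 3 libraries, changes are log2 fold changes ± SE, and members of a list that ran against its majority were named after their values were seen.

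The first comparison asked what IL-1β did to chondrocytes. IL-1β raised many genes of inflammation and 13 of 24 tested matrix-degrading proteases, while 8 proteases fell. Some genes rose from levels near or below detection in control cells. Mmp3 (ENSMUSG00000043613), which encodes the matrix-degrading protease stromelysin-1, rose from 1.83 ± 0.471 to 33940 ± 737 CPM, and Nos2 (ENSMUSG00000020826), the inducible nitric oxide synthase, from 0.0807 ± 0.0265 to 2505 ± 103 CPM. At the same time the main products of cartilage cells were lower. Acan (ENSMUSG00000030607), which encodes the large cartilage proteoglycan aggrecan, fell from 9664 ± 171 to 623.9 ± 25.9 CPM, which is 15.5-fold lower, and Col2a1 (ENSMUSG00000022483), the main collagen of cartilage, fell from 74500 ± 1040 to 15410 ± 539 CPM, which is 4.84-fold lower. The log2 changes were 14.17 for Mmp3, 14.80 for Nos2, −3.95 ± 0.04 for Acan and −2.27 ± 0.03 for Col2a1. Their adjusted p were 1.88e-37, 1.84e-35, 7.56e-31 and 3.34e-28 in edgeR's test. No SE is given for Mmp3 and Nos2, as their low control levels make it too small. In all, 5969 genes rose and 6258 fell among 15502 tested, or 78.9%, and 2860 of those that rose and 3294 of those that fell changed at least 2-fold. The 3 libraries of each group did not overlap for 80% of tested genes, against the 10% that chance gives.

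**Figure D1:**
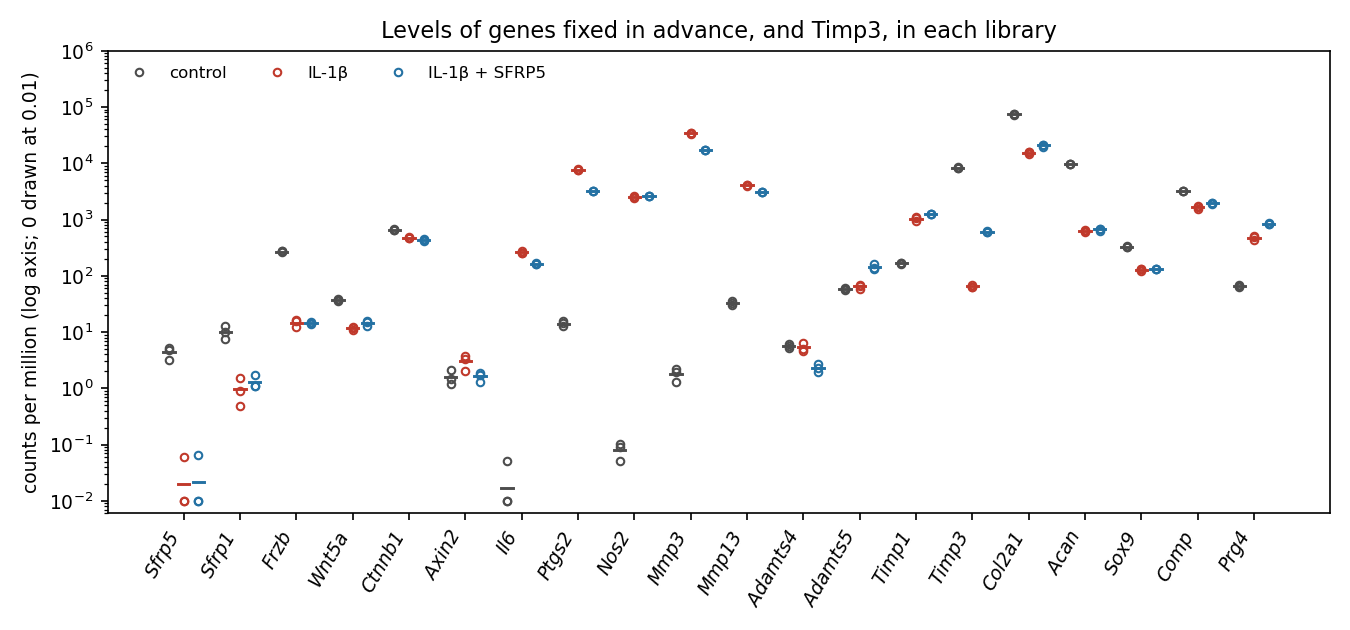
Level of 19 genes fixed in advance and of Timp3 in each library, in CPM on a log axis with 0 drawn at 0.01; circles are the 3 libraries of a group and bars their mean. Mmp3, Nos2 and Ptgs2 lie over 100-fold higher in both IL-1β groups than in control, while Timp3 and Adamts5 differ between the groups with and without SFRP5.

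Many inflammatory cytokines and chemokines rose strongly after IL-1β. Of 27 tested members of this list 22 rose and 5 fell, with a median log2 change of 5.41 (camera, adjusted p = 1.07e-05), although the call was lost at an adjusted p = 0.0552 with an estimated correlation. Cxcl1 and Cxcl5, chemokines that attract neutrophils, reached 3690 and 2550 CPM from 0.899 and 2.94 CPM, and Ccl2, which attracts monocytes, rose 1190-fold. Il6 (ENSMUSG00000025746), which encodes interleukin-6, had 13355 counts over the IL-1β libraries and 1 in control, a ratio of 16300 with an exact interval of 2920 to 643000. Cxcl2 had 2 counts in control and a ratio of 43100 (11900 to 356000), and Ccl20, a chemokine for lymphocytes and dendritic cells, was at least 4340-fold higher, with 0 counts in control. The 5 members that fell were Il1rn, which encodes the IL-1 receptor antagonist, with Csf1, Cxcl12, Cxcl14 and Ccl9.

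All 22 members of the list of NF-κB feedback and target genes rose, with a median of 3.15 (camera, adjusted p = 7.34e-10, and adjusted p = 0.039 with an estimated correlation). They included inhibitors of the pathway itself: Nfkbia, which encodes IκBα, rose by 6.49 on the log2 scale to 658.1 ± 2.95 CPM, Tnfaip3, which encodes the ubiquitin-editing enzyme A20, by 7.68, and Zc3h12a, a nuclease for cytokine mRNAs, by 5.16. Of 20 acute phase and complement genes 17 rose and 0 fell, with 1 more falling when adjusted over the list alone. Their median was 2.40 (camera, adjusted p = 1.96e-07, and adjusted p = 0.039 with an estimated correlation). Saa3, a serum amyloid protein, rose from 0.434 to 13040 ± 573 CPM, and Lcn2, an iron-sequestering protein, rose 415-fold. Of 18 prostaglandin and nitric oxide genes 12 rose and 5 fell, with a median of 2.33 (camera, adjusted p = 0.0103, and adjusted p = 0.133 with an estimated correlation). Ptgs2, which encodes cyclooxygenase-2, rose 539-fold to 7632 ± 177 CPM, and Ptges, which makes prostaglandin E2, rose 102-fold. The 5 that fell were Hpgd, which breaks down prostaglandins, the phospholipases Pla2g5 and Pla2g2e, the prostacyclin synthase Ptgis and the receptor Ptger1. Of 20 interferon-stimulated genes 9 rose and 6 fell, and the list was not called (median 0.29, camera, adjusted p = 0.534). Gbp2, a guanylate-binding protein, rose by 4.95 while Ifit2 fell by 2.85.

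Some transcripts that are markers of immune cells were higher in the same libraries, but most listed markers had too few counts to be tested. Tested were 6 of 15 macrophage, 2 of 11 neutrophil, 2 of 7 osteoclast and 3 of 9 endothelial markers. Of 6 tested macrophage markers 4 rose and 1 fell, with a median of 1.4, and the list was not called (camera, adjusted p = 0.19). Cd14, a receptor for bacterial lipopolysaccharide, rose from 1.25 to 27.38 CPM, Mrc1 from 1.62 to 11.2 CPM and Cd68 from 1.46 to 6.80 CPM, whereas Laptm5 fell from 3.24 to 0.868 CPM. Both tested neutrophil markers rose, S100a8 from 0 to 75 counts, at least 30.5-fold, and Camp from 1 to 263 counts, a ratio of 321 (57.1 to 12700). Their median of 7.79 was 6.37 with S100a8 at its bound. Both osteoclast markers rose too, Acp5 by 0.97 and Ctsk by 0.29. Of 3 endothelial markers 2 rose, with a median of 2.18 (camera, adjusted p = 0.493), among them Tek at 1.35 CPM. None of the lymphocyte and erythroid markers on the fixed lists had enough counts to be tested, but Trdc, the constant region of the T cell receptor δ chain and not on a list, was at 153.5 CPM with IL-1β and had 0 counts in control.

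The matrix of cartilage and the genes that build it were lower after IL-1β. Of 25 genes of cartilage matrix and chondrocyte identity 23 fell and 2 rose, with a median of −1.35 (camera, adjusted p = 3.6e-07, and adjusted p = 0.132 with an estimated correlation). Hapln1, the link protein that holds aggrecan on hyaluronan, fell from 1232 to 68.01 CPM, and Col11a1, a collagen of the cartilage fibril, fell from 14550 CPM by 2.56 on the log2 scale. Sox9, the transcription factor of the chondrocyte lineage, fell by 1.35 ± 0.04 on the log2 scale, and Comp, a matrix protein of cartilage, by 0.97. The 2 that rose were Cilp2 and Prg4, which encodes the joint lubricant lubricin and rose 7.27-fold to 475.4 ± 34.5 CPM. Of 25 genes of glycosaminoglycan synthesis 18 fell and 5 rose (6 rose when adjusted over the list alone), with a median of −0.83 (camera, adjusted p = 0.00569, and adjusted p = 0.132 with an estimated correlation). Csgalnact1, which starts chondroitin sulfate chains, fell by 4.72 on the log2 scale, and the sulfate transporter Slc26a2 fell by 4.56. The 5 that rose were Has1, a hyaluronan synthase, Ugdh, which makes the sugar precursor of these chains, Ext1, Chst15 and Papss1.

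The enzymes that degrade matrix went in both directions. Of 24 tested proteases 13 rose and 8 fell (14 rose when adjusted over the list alone), and the list was not called (median 0.56, camera, adjusted p = 0.135). Mmp13, the collagenase that cleaves collagen of cartilage, rose 125-fold to 4119 ± 85.6 CPM, and Mmp10, stromelysin-2, from 0.0994 to 236.8 ± 1.76 CPM. The aggrecanase Adamts4 was at 5.70 ± 0.463 CPM in control and 5.35 ± 0.908 CPM with IL-1β (adjusted p = 0.633). Adamts5, the other main aggrecanase, was at 58.67 ± 2.29 and 64.84 ± 5.64 CPM, a log2 difference of 0.15 ± 0.07 that missed the threshold (adjusted p = 0.0548). It passed the threshold without control library 3 (0.0481), IL-1β library 1 (0.0033) or SFRP5 library 1 (0.0476), 2 (0.0193) or 3 (0.0181). Adamts5 also passed it with RLE factors (0.0292), the replicate number as a block (0.0319), no low-count filter (0.00532) and only the 6 libraries compared (0.0207). It did not pass with DESeq2, robust dispersions or upper-quartile factors, the last of which left a difference near 0. Among 15 protease inhibitors 10 rose and 4 fell, with no call for the list (median 1.25, camera, adjusted p = 0.13). Timp3 (ENSMUSG00000020044), a matrix-bound inhibitor of metalloproteases and aggrecanases, fell from 8369 ± 117 to 65.09 ± 2.72 CPM, a log2 change of −7.01, whereas Timp1 rose from 168.3 ± 3.05 to 1028 ± 84.3 CPM. Reck, Timp2 and Cst3 were the others that fell, and Slpi, an inhibitor of serine proteases, rose by 5.57.

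Most Wnt genes measured were lower after IL-1β. Sfrp5 itself (ENSMUSG00000018822) had 269 counts over the control libraries, or 4.35 ± 1.07 CPM, and 1 count over the IL-1β libraries, a ratio of 221 with an exact interval of 39.3 to 8740 (adjusted p = 1.93e-11). Of 10 secreted Wnt antagonists 9 fell and Kremen1, a receptor for the Dickkopf antagonists, rose, with a median of −2.98 (camera, adjusted p = 0.00569, and adjusted p = 0.0732 with an estimated correlation). Frzb, a relative of Sfrp5 made by chondrocytes, fell from 269.8 ± 3.32 to 14.68 ± 2.26 CPM, Sfrp1 from 10.07 ± 2.65 to 0.977 ± 0.529 CPM and Dkk3 from 246.5 to 4.81 CPM. Of 24 tested Wnt ligands and receptors 14 fell and 6 rose, without a call for the list (median −1.30, camera, adjusted p = 0.095). The receptors Fzd9, Fzd8 and Fzd2 fell by 6.38, 3.66 and 3.12 on the log2 scale, Fzd1 rose by 2.02, and the ligand Wnt5a fell by 1.67. Ctnnb1, which encodes β-catenin, fell by 0.46. Of 19 targets of Wnt/β-catenin signalling 7 rose and 10 fell, and this list was not called (median −0.69, camera, adjusted p = 0.695). Axin2, a feedback inhibitor used as a readout of the pathway, rose from 1.59 ± 0.492 to 3.04 ± 0.883 CPM (adjusted p = 0.00359). Cd44, the hyaluronan receptor, rose by 4.48, and the cyclin Ccnd1 fell by 3.03.

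Cell cycle genes fell as a group after IL-1β. Of 25 members 23 fell, with a median of −3.50 (camera, adjusted p = 1.85e-07, and adjusted p = 0.039 with an estimated correlation), and the DNA synthesis genes Pcna and Tyms rose. The proliferation marker Mki67 fell from 147.9 to 6.53 ± 1.45 CPM and Ccna2, a cyclin of DNA replication and mitosis, from 43.26 to 1.25 CPM. Of 19 p53 target, senescence and apoptosis genes 14 rose and 3 fell, with a median of 0.79 (camera, adjusted p = 0.00828, and adjusted p = 0.0732 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose from 318.8 to 1445 CPM, and Sesn1 and Bcl2 were among those that fell.

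All 25 genes of glycolysis and hypoxia rose, with a median of 3.10 (camera, adjusted p = 7.03e-12, and adjusted p = 0.039 with an estimated correlation). The glucose transporter Slc2a1 rose 24.9-fold to 3090 CPM and the hexokinase Hk2 by 3.69. Of 21 antioxidant and NRF2 target genes 19 rose and Gpx4 fell, with a median of 2.89 (camera, adjusted p = 1.85e-07, and adjusted p = 0.158 with an estimated correlation). Slc7a11 (ENSMUSG00000027737), the cystine transporter that feeds glutathione synthesis, rose 51.4-fold to 1422 ± 12.1 CPM, and the metallothionein Mt2 rose by 6.02. The unfolded protein and amino acid stress list had 6 genes that rose and 9 that fell among 20. Its median of −0.08 and mean of 0.08 differed in sign, and it was not called (camera, down, adjusted p = 0.77). Cholesterol genes were not called either, with 5 up and 11 down of 20 (median −0.29, camera, adjusted p = 0.369), although Sqle, which encodes squalene epoxidase, rose by 2.52. Immediate early and heat shock genes rose in 10 and fell in 7 of 19 cases (median 0.23, camera, adjusted p = 0.327), with Ier3 up by 6.50. Of 12 mitochondrially encoded transcripts 4 rose and 6 fell (median −0.08, camera, adjusted p = 0.572).

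Genes of related lineages and programmes were mostly lower. Of 21 fibroblast-type collagen and dedifferentiation genes 15 fell and 5 rose (6 rose when adjusted over the list alone), with a median of −0.82 (camera, adjusted p = 0.0125, and adjusted p = 0.235 with an estimated correlation). Col1a2, a collagen of bone and fibrous tissue, fell from 5659 to 1684 CPM and the contractile actin Acta2 by 3.83, while the small proteoglycan Dcn rose by 2.62 and Col5a2, Col6a1, Fn1 and Lum rose as well. Of 18 genes of hypertrophy and mineralization 6 rose and 11 fell (median −1.25, camera, adjusted p = 0.3), with Spp1, which encodes osteopontin, up by 2.90 and the channel Panx3 down by 5.99. The TGF-β and BMP list had 12 up and 15 down of 27 (median −0.47, camera, adjusted p = 0.493), with the activin subunit Inhba up by 5.34. All 6 tested adipocyte markers fell, with a median of −2.30 (camera, adjusted p = 0.0117, and adjusted p = 0.101 with an estimated correlation), among them the lipoprotein lipase Lpl by 2.26. Of 6 osteoblast and osteocyte markers 5 fell, with a median of −2.21 and no call for the list (camera, adjusted p = 0.058). That list passed the threshold without control library 1 (0.0337), IL-1β library 1 (0.0306) or 3 (0.0116), or any of the SFRP5 libraries (0.0285, 0.0291 and 0.0375). Sp7, a transcription factor of osteoblasts, fell by 6.53 and Col1a1 by 1.49. Of 6 skeletal muscle markers 4 fell (median −1.74, camera, adjusted p = 0.131), with Tnnt3 at 1.86 CPM in control. Synovial fibroblast markers went both ways, 2 up and 3 down of 8, with a median of −0.03 against a mean of 0.18 (camera, up, adjusted p = 0.779). Pdpn rose by 3.49 and Thy1 fell by 2.28.

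By the fixed rule, the largest increases also took in Ccl5 (9440-fold), the serpin Serpinb2 (at least 1250-fold), Trdc (at least 3150-fold) and H2-Q2 (at least 988-fold). The largest decreases were led by Smpd3, a neutral sphingomyelinase needed for normal cartilage and bone, which fell from 850.9 ± 0.539 to 0.470 ± 0.194 CPM. Gdf10, a growth factor of the BMP family, had 2 counts against 4001 in control, a ratio of 1640 (454 to 13500), and Arsi had 3 against 2499, a ratio of 683 (233 to 3310). The others had 0 counts in IL-1β libraries and were lower by at least 147-fold (Calml3), 119-fold (the angiotensin receptor Agtr2), 110-fold (Acss3 and Edar), 103-fold (Gask1a), 94.3-fold (Zfp385c) and 84.5-fold (Ttc22). With upper-quartile factors the median log2 change of all genes was −0.18 in place of −0.0325 in this comparison, and −0.157 in place of −0.0232 for both treatments against control, so a change of about that size depends on the scaling. Of 29 lists with 3 or more tested members 7 were called up and 6 down, and 4 of these 13 calls held with an estimated correlation.

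The second comparison asked what recombinant SFRP5 changed in cells that received IL-1β. Added SFRP5 lowered many inflammatory and oxidative stress genes that IL-1β had raised, and raised part of the matrix and cell cycle genes that IL-1β had lowered. The adhesion molecule Icam1 (ENSMUSG00000037405) fell from 949.2 ± 140 to 168.8 ± 22.1 CPM, a log2 change of −2.49 (adjusted p = 8.9e-18), and Slc7a11 fell from 1422 ± 12.1 to 312.3 ± 11.9 CPM, a change of −2.19 (adjusted p = 2.11e-23). Timp3 rose 9.39-fold from 65.09 ± 2.72 to 611.2 ± 14.1 CPM (adjusted p = 1.21e-27), and Mmp10 fell from 236.8 ± 1.76 to 36.41 ± 4.09 CPM (adjusted p = 3.5e-21). Most changes were small. Of 15502 genes 2420 rose and 2438 fell in edgeR's test, or 31.3%, with a median absolute log2 change of 0.36 among those called, against 1.01 in the first comparison, and 342 and 296 changed at least 2-fold. The libraries of the 2 groups did not overlap for 40.8% of genes, against 10% by chance.

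The largest increase under the fixed rule was that of Ccn5 (ENSMUSG00000027656), a matricellular protein of the CCN family, which rose 26.3-fold from 1.17 ± 0.119 to 30.69 ± 3.95 CPM and was at 244.1 CPM in control. After Timp3 and the chemokine Cxcl14, which rose by 3.01 ± 0.18 on the log2 scale, followed Masp1, a protease of the lectin pathway of complement (2.38), the protease Prss23 (2.31), Camk2b (2.22), Ppp1r1b (2.12), the calcineurin regulator Rcan2 (2.03), Pappa, a protease that releases insulin-like growth factors (2.00), and Cbr2 (2.00). The largest decrease was that of Slc7a8, an amino acid transporter, from 64.97 ± 5.53 to 7.5 ± 0.807 CPM (log2 −3.12, adjusted p = 6.94e-19). Besides Mmp10 and Icam1, the cytokine genes Il36g (−2.55) and Il12b (−2.34), the metallothionein Mt3 (−2.38), the channel-like Tmc3 (−2.37) and Lilrb4b (−2.35) were among the 10 largest. Lilrb4a (−2.50) and the glutathione transferase Gsta1 (−2.38) were as well, but 29.0% and 81.8% of their 100-base windows occur in other genes, so their counts are uncertain.

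The lists of cytokines and chemokines, NF-κB genes and interferon-stimulated genes fell with SFRP5. Of 27 cytokines and chemokines 18 fell and 3 rose (18 and 4 when adjusted over the list alone), with a median of −0.80 (camera, adjusted p = 4.19e-07, and adjusted p = 0.0408 with an estimated correlation). Cxcl2 fell from 1399 ± 80.7 to 355.3 CPM, Ccl5 from 1290 to 329.8 CPM, Cxcl1 from 3690 to 1895 CPM and Il6 from 264.5 ± 14.6 to 162.5 ± 5.59 CPM. The 3 that rose were Cxcl14, Cxcl12 and Tnfsf11, which encodes RANKL. Of 22 NF-κB feedback and target genes 18 fell and 2 rose (19 and 2 when adjusted over the list alone), with a median of −0.62 (camera, adjusted p = 1.25e-09, and adjusted p = 0.0408 with an estimated correlation). Birc3, an inhibitor of apoptosis, fell by 1.67, Tnfaip3 by 1.49 and Nfkbia by 0.90, while the atypical IκB genes Nfkbiz and Bcl3 rose by 0.58 and 0.82. Of 20 interferon-stimulated genes 9 fell and 0 rose (13 fell when adjusted over the list alone), with a median of −0.54 (camera, adjusted p = 4.28e-05, and adjusted p = 0.0408 with an estimated correlation). Gbp2 fell from 74.31 to 29.54 CPM and Ddx58, the viral RNA sensor RIG-I, from 29.02 to 17.95 CPM.

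Macrophage markers were lower beside them. Of 6 tested, 3 fell and 0 rose, with a median of −0.36 (camera, adjusted p = 0.0402), a call lost with an estimated correlation (adjusted p = 0.169). It was also lost without control library 2 (0.0589) or 3 (0.0576), IL-1β library 3 (0.0728) or SFRP5 library 1 (0.11) or 3 (0.0776). The replicate number as a block ended it too (0.0538). Mrc1 fell from 11.2 to 5.54 CPM, Cd14 from 27.38 to 18.56 CPM and Csf1r, the receptor of the macrophage growth factor, from 2.27 to 0.915 CPM. Of 2 neutrophil markers neither was called, with a median of −0.16, and of 2 osteoclast markers only Ctsk fell (median −0.12).

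The prostaglandin and nitric oxide list was divided. Of 18 genes 9 fell and 4 rose (10 and 4 when adjusted over the list alone), and with a median of −0.28 the list was not called (camera, adjusted p = 0.0688). It was called without control library 1 (0.0478) or IL-1β library 3 (0.0459). Ptgs2 fell from 7632 ± 177 to 3252 ± 2.37 CPM (adjusted p = 2.16e-19) and Ptges from 945.9 to 517.5 CPM, whereas Nos2 was at 2505 ± 103 CPM without and 2603 ± 27.2 CPM with SFRP5 (adjusted p = 0.223). Those that rose were Hpgd, Ptgis, Ptges2 and Ptger1. Acute phase and complement genes rose in 9 and fell in 3 of 20 cases (9 and 4 when adjusted over the list alone), without a call for the list (median 0.09, camera, adjusted p = 0.107). The long pentraxin Ptx3 rose from 373.3 to 827 CPM and C4b by 0.53, where 16.5% of the windows of C4b occur in other genes. Saa3 fell from 13040 ± 573 to 7156 CPM, C3, the central complement component, from 1735 to 1176 CPM, and Cfb by 0.75.

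Antioxidant and NRF2 target genes fell with SFRP5 in 14 of 21 cases, and Gpx3 rose. Their median was −0.41 (camera, adjusted p = 7.41e-08, and adjusted p = 0.169 with an estimated correlation). Beside Slc7a11, the thioredoxin reductase Txnrd1 fell from 1370 to 501 CPM, the peroxiredoxin Prdx1 from 3851 to 1598 CPM and the sulfiredoxin Srxn1 from 973.6 to 314.5 CPM. The metallothionein Mt1 differed by 0.09 (adjusted p = 0.191). Glycolysis and hypoxia genes fell in 15 and rose in 3 of 25 cases (16 and 4 when adjusted over the list alone), with a median of −0.16 (camera, adjusted p = 0.00147, and adjusted p = 0.169 with an estimated correlation). Ndrg1, a hypoxia-induced gene, fell from 2220 to 1358 CPM and Egln3, which targets hypoxia-inducible factor for degradation, by 0.50, and Pfkfb3, Car9 and P4ha1 were the 3 that rose, by 0.10 to 0.12. Of 12 mitochondrially encoded transcripts 6 fell and 0 rose (7 fell when adjusted over the list alone), with a median of −0.13 (camera, adjusted p = 0.0284, and adjusted p = 0.169 with an estimated correlation). That call was lost without IL-1β library 1 (0.0569) or SFRP5 library 1 (0.0535).

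Cartilage genes rose in part with SFRP5. Of 25 members of the cartilage matrix list 11 rose, Col11a2 fell by 0.14 and 13 were not called, with a median of 0.13 (camera, adjusted p = 0.00147, and adjusted p = 0.241 with an estimated correlation). Col2a1 rose 1.35-fold to 20770 ± 805 CPM (adjusted p = 5.77e-12), Hapln1 from 68.01 to 120.6 CPM, Prg4 1.78-fold to 844.5 ± 15.1 CPM and Comp by 0.25. Sox6, a partner of Sox9 in chondrocytes, rose from 20.04 to 49.77 CPM, while Sox9 was at 129.3 and 130.2 CPM (adjusted p = 0.892). Acan rose by 0.10 ± 0.03 on the log2 scale, from 623.9 ± 25.9 to 668.8 ± 26.5 CPM (adjusted p = 0.0272). That call was lost without IL-1β library 3 (0.119) or SFRP5 library 1 (0.114) or 2 (0.122), and with only the 6 libraries compared (0.0816). Of 25 glycosaminoglycan genes 11 rose and 3 fell (11 and 4 when adjusted over the list alone), with a median of 0.13 (camera, adjusted p = 0.0115, and adjusted p = 0.169 with an estimated correlation). Csgalnact1 rose by 1.4 and Dse, which makes dermatan sulfate, by 0.68, and those that fell were the sulfotransferases Chst12 and Chst15 and the galactosyltransferase B4galt7.

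Matrix proteases and their inhibitors changed in both directions. Of 24 proteases 8 rose and 12 fell (median −0.22, camera, adjusted p = 0.208). Mmp3 fell by 0.97 on the log2 scale, from 33940 ± 737 to 17340 ± 68.7 CPM, Mmp13 by 0.40, from 4119 ± 85.6 to 3115 ± 25.9 CPM, and the plasminogen activators Plau and Plat by 1.33 and 1.47. The 2 aggrecanases moved apart: Adamts5 (ENSMUSG00000022894) rose 2.25-fold from 64.84 ± 5.64 to 146.1 ± 15.7 CPM (adjusted p = 2.72e-13), and Adamts4 fell by 1.21, from 5.35 ± 0.908 to 2.30 ± 0.358 CPM (adjusted p = 2.28e-05). Of 15 protease inhibitors 9 rose and 3 fell (median 0.14, camera, adjusted p = 0.106). Timp1 rose by 0.29, and Serpinb2, Slpi and Spint2 fell.

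Among Wnt genes the changes with SFRP5 were modest. Of 24 ligands and receptors 11 rose and 3 fell (12 and 3 when adjusted over the list alone), with a median of 0.24 (camera, adjusted p = 0.0485, and adjusted p = 0.169 with an estimated correlation). The call was lost without control library 2 (0.0573) or 3 (0.0553), IL-1β library 1 (0.0569) or SFRP5 library 1 (0.0693) or 3 (0.0513). The replicate number as a block ended this call too (0.0538). The receptors Fzd2, Fzd8 and Ror1 rose by 0.73, 0.82 and 1.09, and Wnt5a rose from 11.59 to 14.65 CPM (adjusted p = 0.008), while Wnt11, Fzd1 and Ctnnb1 fell. Ctnnb1 fell by 0.14 (adjusted p = 0.00663), a call lost without SFRP5 library 2 (0.061). Of 10 secreted antagonists 3 rose and 0 fell (median 0.25, camera, adjusted p = 0.0712), with Dkk3 up by 1.71. Endogenous Sfrp5 had 1 count over each of the 2 groups, below the 3 counts needed for a fold (adjusted p = 0.991), and Frzb was at 14.68 and 14.55 CPM (adjusted p = 0.966). Sfrp1 differed by 0.39 (adjusted p = 0.467). Of 19 Wnt/β-catenin targets 3 rose and 6 fell (3 and 7 when adjusted over the list alone), without a call (median −0.19, camera, adjusted p = 0.318). Cd44 fell from 1625 to 738.3 CPM, and Ccnd1, Myc and Ccn4 rose by 0.38 to 0.54. Axin2 fell by 0.92 ± 0.29 to 1.63 ± 0.311 CPM (adjusted p = 0.0156), a call lost without IL-1β library 1 (0.0908) or 3 (0.0517) or SFRP5 library 1 (0.0854).

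Cell cycle genes rose with SFRP5 in 16 of 25 cases and fell in 0 (18 rose when adjusted over the list alone), with a median of 0.66 (camera, adjusted p = 6.87e-06, and adjusted p = 0.0408 with an estimated correlation). Mki67 rose from 6.53 ± 1.45 to 15.33 ± 1.91 CPM and the ribonucleotide reductase subunit Rrm2 from 4.71 to 11.9 CPM, and both stayed below control. Fibroblast-type collagens and related genes rose in 15 of 21 cases and fell in 0, with a median of 0.27 (camera, adjusted p = 2.45e-07, and adjusted p = 0.05 with an estimated correlation). Col3a1, a fibrillar collagen of soft tissue, rose from 1230 to 2378 CPM and the growth factor receptor Pdgfra by 0.87. Of 18 hypertrophy and mineralization genes 6 rose and Vegfa fell (7 rose when adjusted over the list alone), with a median of 0.20 (camera, adjusted p = 0.0245, and adjusted p = 0.127 with an estimated correlation). Spp1 rose from 1886 to 2705 CPM. Of 19 p53 and senescence genes 9 rose and 2 fell (10 and 2 when adjusted over the list alone), with a median of 0.14 (camera, adjusted p = 0.0229, and adjusted p = 0.127 with an estimated correlation), a call lost without IL-1β library 1 (0.0501). Trp53inp1 rose by 0.32, and Gdf15 and Cdkn1a fell.

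The remaining lists were not called with SFRP5. Of 27 TGF-β and BMP genes 13 rose and 5 fell (13 and 6 when adjusted over the list alone, median 0.17, camera, adjusted p = 0.0702). Ltbp1, which stores TGF-β in the matrix, rose from 61.93 to 125.1 CPM, and the BMP target Id2 fell by 1.00. Immediate early and heat shock genes fell in 9 and rose in 2 of 19 cases (10 and 3 when adjusted over the list alone, median −0.33, camera, adjusted p = 0.0712), with a call without IL-1β library 3 (0.0108) or SFRP5 library 1 (0.0493). Junb fell by 0.63. Of 20 unfolded protein and amino acid stress genes 10 fell and 3 rose (11 and 4 when adjusted over the list alone, median −0.10, camera, adjusted p = 0.0702), with a call without IL-1β library 3 (0.0274). The chaperone Hspa5 fell by 0.29. Of 20 cholesterol genes 1 rose and 4 fell (median −0.04, camera, adjusted p = 0.663). Skeletal muscle markers had a median of 1.24 with 1 of 6 called and 0 when adjusted over the list alone (camera, adjusted p = 0.0688), and the list was called without control library 1 (0.0478) or IL-1β library 3 (0.0493). Of 6 osteoblast markers 2 rose (median 0.18, camera, adjusted p = 0.303) and of 8 synovial fibroblast markers Prg4 rose and Pdpn fell (median 0.22, camera, adjusted p = 0.709). Adipocyte markers had 1 up and 1 down of 6, with a median of −0.34 and a mean of 0.34 (camera, down, adjusted p = 0.663), and of 3 endothelial markers 1 fell, with a median of 0.41 and a mean of −0.07 (camera, up, adjusted p = 0.837). In total 7 lists were called up and 7 down, and 4 of the 14 held with an estimated correlation.

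**Figure D2:**
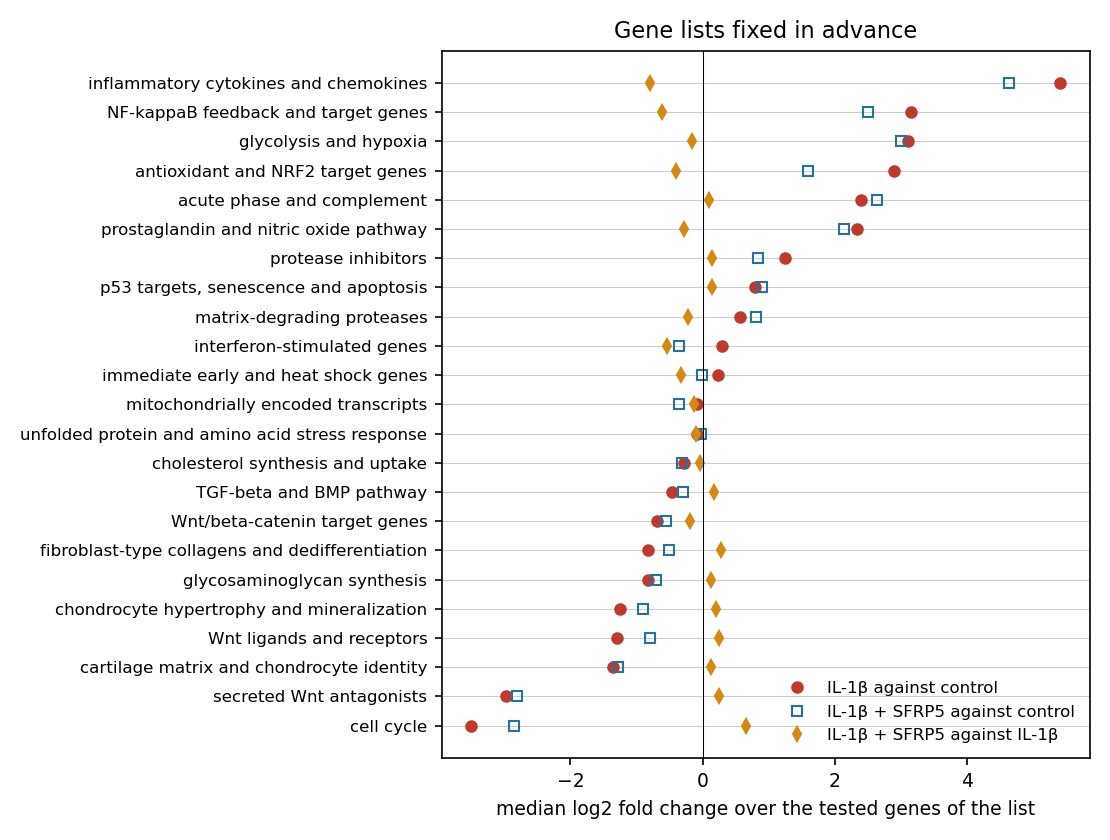
Median log2 fold change over the tested genes of each of 23 gene lists, for IL-1β against control (circles), IL-1β with SFRP5 against control (squares) and IL-1β with SFRP5 against IL-1β (diamonds). The lists raised most by IL-1β, such as cytokines with a median of 5.41 and NF-κB genes with 3.15, have diamonds left of 0 except acute phase genes, and cell cycle genes, with a median of −3.50, have theirs at 0.66.

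The third comparison asked how far cells given both IL-1β and SFRP5 still stood from control. Inflammatory genes stayed high in them and cartilage matrix genes stayed low. Nos2 was 14.85 higher than in control on the log2 scale, Mmp3 13.20 and Saa3 14.03, Ptgs2 was 230-fold and Mmp13 94.7-fold higher, and Il6 had 8574 counts against 1, a ratio of 10000 (1800 to 397000). Acan was lower with a log2 change of −3.85 (adjusted p = 1.51e-30) and Col2a1 with −1.84 (adjusted p = 2.53e-26), and the changes of Sox9 and Comp were −1.34 and −0.72. In edgeR's test 5788 genes were higher and 6040 lower than in control, or 76.3%, with 2661 and 2948 of them at least 2-fold, and the groups did not overlap for 78.2% of genes, against 10% by chance.

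Lists of NF-κB, cytokine, acute phase, prostaglandin, glycolysis, NRF2 and p53 genes stayed above control. Among 22 NF-κB genes 21 were higher (median 2.50, camera, adjusted p = 3.95e-09, and adjusted p = 0.044 with an estimated correlation), with Nfkbia up by 5.59. Vcam1, an adhesion molecule, was the 1 not called, with a difference of 0.21 (adjusted p = 0.0735). Cytokines and chemokines were higher in 23 and lower in 4 of 27 cases (median 4.63, camera, adjusted p = 8.45e-06, and adjusted p = 0.044 with an estimated correlation). Acute phase genes were higher in 17 of 20 cases (median 2.63, camera, adjusted p = 2.57e-08, and adjusted p = 0.044 with an estimated correlation), with Lcn2 at 9916 CPM, and prostaglandin and nitric oxide genes in 12 of 18, with 5 lower (median 2.14, camera, adjusted p = 0.00657, and adjusted p = 0.128 with an estimated correlation). Glycolysis and hypoxia genes were higher in 25 of 25 cases (median 3.00, camera, adjusted p = 1.82e-12, and adjusted p = 0.044 with an estimated correlation) and NRF2 targets in 19 of 21, with Sod1 and Gpx4 lower (median 1.59, camera, adjusted p = 8.93e-07, and adjusted p = 0.19 with an estimated correlation). Slc7a11 stood 11.3-fold above control. The p53 and senescence list had 14 higher and 2 lower of 19 (median 0.90, camera, adjusted p = 0.00168, and adjusted p = 0.044 with an estimated correlation). The interferon list, not called with IL-1β alone, was not called here either: of 20 genes 5 were higher and 9 lower, with a median of −0.36 and a mean of 0.18 (camera, down, adjusted p = 0.514), Gbp2 being up by 3.62 and Ddx58 down by 1.09.

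Cartilage, Wnt antagonist and cell cycle lists stayed below control. Cartilage matrix genes were lower in 21 and higher in 2 of 25 cases (median −1.28, camera, adjusted p = 1.26e-06, and adjusted p = 0.128 with an estimated correlation). Of 25 glycosaminoglycan genes 16 were lower and 4 higher (median −0.70, camera, adjusted p = 0.00538, and adjusted p = 0.128 with an estimated correlation). Secreted Wnt antagonists were lower in 9 of 10 cases, with Kremen1 higher (median −2.81, camera, adjusted p = 0.00538, and adjusted p = 0.0723 with an estimated correlation). Sfrp5 had 1 count, a ratio of 230 below control (40.9 to 9100), and Frzb had a log2 change of −4.21. Wnt ligands and receptors were lower in 13 and higher in 9 of 24 cases (median −0.80, camera, adjusted p = 0.21), and Wnt/β-catenin targets were lower in 11 and higher in 5 of 19 (median −0.56, camera, adjusted p = 0.412). Axin2 was at 1.59 ± 0.492 CPM in control and 1.63 ± 0.311 CPM with both (adjusted p = 0.944). Cell cycle genes were lower in 23 and higher in 2 of 25 cases (median −2.85, camera, adjusted p = 1.93e-07, and adjusted p = 0.04 with an estimated correlation), with Mki67 at −3.27.

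Some genes stood further from control with both treatments than with IL-1β alone. Prg4 was 12.9-fold higher than in control, Timp1 7.45-fold, and Adamts5 2.49-fold (adjusted p = 1.06e-15), whereas Adamts4 was lower, with a log2 change of −1.30 (adjusted p = 9.26e-07). Timp3 was still lower, with −3.78. Protease inhibitors were higher in 9 and lower in 4 of 15 cases (median 0.84, camera, adjusted p = 0.129), and proteases higher in 13 and lower in 8 of 24 (median 0.81, camera, adjusted p = 0.144). Under the fixed rule the largest increases took in Ccl20 (at least 2440-fold), Cxcl2 (a ratio of 11000, 3040 to 90600), H2-Q2 (at least 812-fold) and Trdc (at least 652-fold). Saa2 and Saa1 were higher by at least 467-fold and 455-fold, with 9.8% of their windows shared with other genes. The largest decreases were those of Aldh1a7 (at least 324-fold), Calml3 (at least 153-fold), Smpd3 (−10.39), Slc16a14 (−8.15), the cell cycle inhibitor Cdkn1c (−7.34), Ncmap (−7.30) and Gdf10 (−7.25). Gjc3, Cmtm5 and Smim5 had 1 count with both treatments, with ratios below control of 857 (153 to 33900), 603 (108 to 23900) and 322 (57.4 to 12700).

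The other lists were mostly not called in this comparison. Fibroblast-type collagens were higher in 6 and lower in 14 of 21 cases (median −0.51, camera, adjusted p = 0.105), hypertrophy genes in 6 and 11 of 18 (median −0.90, camera, adjusted p = 0.451), TGF-β and BMP genes in 11 and 14 of 27 (median −0.30, camera, adjusted p = 0.605) and cholesterol genes in 6 and 11 of 20 (median −0.32, camera, adjusted p = 0.371). Unfolded protein and amino acid stress genes were higher in 8 and lower in 9 of 20 (median −0.03, camera, adjusted p = 0.677), and mitochondrially encoded transcripts higher in 2 and lower in 7 of 12 (median −0.36, camera, adjusted p = 0.227). Immediate early and heat shock genes were higher in 8 and lower in 9 of 19, with a median of −0.01 and a mean of 0.58 (camera, up, adjusted p = 0.646). Adipocyte markers were lower in 6 of 6 cases (median −2.85, camera, adjusted p = 0.00657, and adjusted p = 0.0793 with an estimated correlation). Osteoblast markers were lower in 5 of 6 (median −1.73, camera, adjusted p = 0.083), and this list was called without control library 1 (0.0462), any IL-1β library (0.0325, 0.0498 and 0.0363) or any SFRP5 library (0.0402, 0.0419 and 0.0499). Macrophage markers were higher in 3 and lower in 2 of 6 (median 0.81, camera, adjusted p = 0.519), endothelial markers higher in 2 of 3 (median 2.59, camera, adjusted p = 0.355), and skeletal muscle markers lower in 2 of 6 (median −0.44, camera, adjusted p = 0.451). Synovial fibroblast markers were higher in 3 and lower in 2 of 8, with a median of −0.03 and a mean of 0.29 (camera, up, adjusted p = 0.71). Both tested neutrophil markers were higher (median 7.63, or 6.20 with S100a8 at its bound). Of 2 tested osteoclast markers Acp5 was higher (median 0.51). Of 29 lists 7 were called up and 5 down, and 6 of the 12 held with an estimated correlation.

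The last comparison asked whether genes moved by IL-1β moved back when SFRP5 was added. Among the 10 genes that the fixed rule took for this, IL-1β raised and SFRP5 lowered Slc7a11, Mmp10, Txnrd1, Cxcl2, Cxcl3, the protein C receptor Procr, the peroxiredoxin Prdx6 and the carboxypeptidase Cpm, and IL-1β lowered and SFRP5 raised Timp3 and Ccn5. Procr went from 6.29 CPM in control to 961.3 with IL-1β and 312.8 with SFRP5, Prdx6 from 58.57 to 1694 and 450.1 CPM, and Cpm from 30.95 to 365.8 and 101.7 CPM. Of the genes called in both comparisons 1914 rose with IL-1β and fell with SFRP5, and 1636 fell and then rose, so that 3550 of 4378, or 81.1%, moved in opposite directions. The other 828 moved the same way in both, 558 up and 270 down. Independent lists of these sizes would share 939 and 977 genes in opposite directions, and 932 and 984 in the same direction. Because both comparisons contain the IL-1β libraries, chance alone pushes them apart. In 20 simulations without an SFRP5 effect only 0 to 6 genes were called in both comparisons, so their share in opposite directions, with a mean of 65.8% and a range of 0 to 100%, is a weak measure of chance for the 81.1%. Over all genes the covariance of the 2 changes was −0.039 in these simulations, which keep the shared libraries, against −0.534 observed. For spread that is independent between genes, this argues against the shared libraries as the source of most of the opposite movement. Each gene was drawn independently in the simulations, so deviations of the IL-1β libraries common to many genes were not part of them. Some of the movement may thus still come from the shared libraries, and 3 libraries cannot be split into parts of at least 2.

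**Figure D3:**
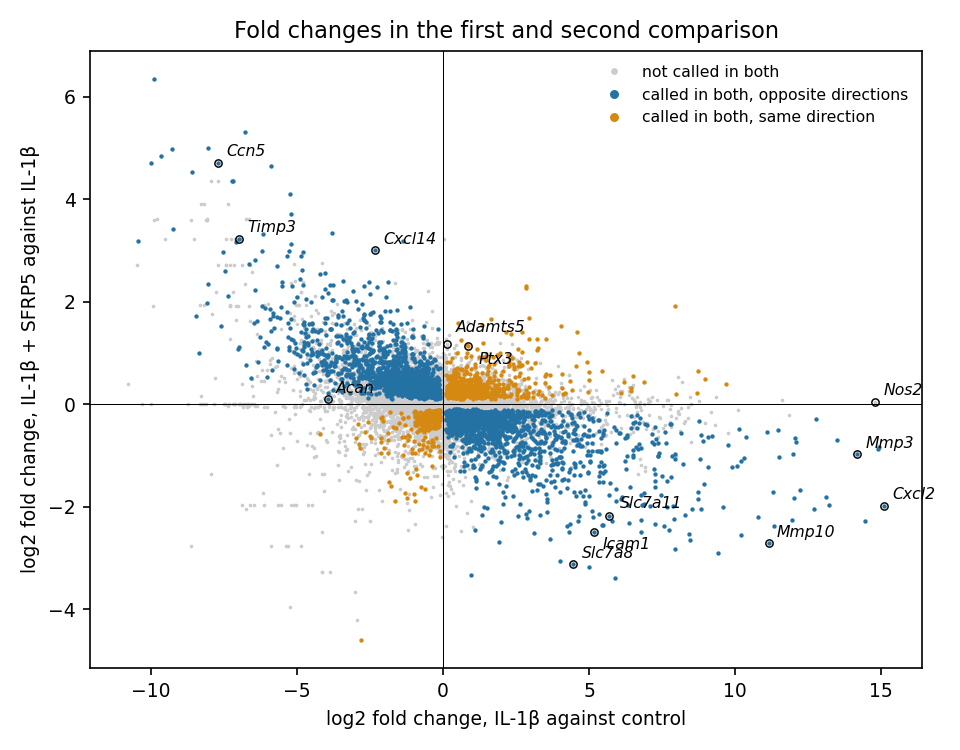
Log2 fold change of each tested gene with IL-1β against control (horizontal axis) and with IL-1β and SFRP5 against IL-1β alone (vertical axis), coloured by whether edgeR called the gene in both comparisons. The 3550 genes called in opposite directions lie at the upper left and lower right, and 828 genes called in the same direction at the upper right and lower left.

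The way back was short for most genes. Over 6154 genes that IL-1β changed at least 2-fold, the median share of the log2 change that was undone with SFRP5 was 11.9%, against 0.263% in the simulations, with 7.98% for genes raised and 16.4% for genes lowered by IL-1β. Of the 3550 genes 2858 were still called against control on the side to which IL-1β had moved them, 605 were not called against control, and 87 were called on the other side of control. Across genes the changes of the 2 comparisons had a correlation of −0.488 (−0.069 in the simulations) and a covariance of −0.534 (−0.039 in the simulations), a difference in covariance of −0.495.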

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

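Every alternative here was planned before any result was seen, and none was added afterwards. For the numbers of called genes only the demand for a fold of at least 2 moved a count by over 1.5 times, by its own construction: to 2860 higher and 3294 lower for IL-1β against control, 342 and 296 for SFRP5 added to IL-1β, 2661 and 2948 for both against control, and 521 genes moved in opposite directions. Under DESeq2 the counts were 6180 and 6190, 1901 and 2119, and 5855 and 5862, and under upper-quartile factors 5186 and 7150, 2575 and 2247, and 5008 and 6947. Leaving out 1 library gave 5853 to 6177 higher and 6072 to 6435 lower with IL-1β, 2045 to 2333 and 2029 to 2399 with SFRP5 added, 5629 to 6019 and 5853 to 6103 for both against control, and 3030 to 3428 genes moved in opposite directions. In none of these settings was a gene called in both the main and the other setting with opposite signs. Of 7094 values of named genes 7045 kept their direction and side of the threshold, and of 1131 values of lists 1034 did. Replicate numbers did not pair the libraries: same-numbered libraries deviated from their group means with r of −0.0364 to 0.0402, and 0 of 9 correlated best with its own number in both other groups. With the replicate number as a block 5937 genes were higher and 6214 lower with IL-1β, 2389 and 2391 with SFRP5 added, and 5761 and 6000 for both against control. The block ended 2 list calls with SFRP5 added, Wnt ligands and receptors (adjusted p = 0.0538) and macrophage markers (adjusted p = 0.0538). Among named genes it changed 1 call, that of Adamts5 with IL-1β, which passed the threshold (adjusted p = 0.0319).

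Camera with an estimated correlation, which is larger than 0.01 where a list's genes vary together, ended these calls. The adjusted p for IL-1β against control became 0.132 for cartilage matrix and for glycosaminoglycan synthesis, 0.0552 for cytokines, 0.133 for prostaglandin and nitric oxide genes, 0.0732 for Wnt antagonists and for p53 targets, 0.235 for fibroblast-type collagens, 0.158 for NRF2 targets and 0.101 for adipocyte markers. With SFRP5 added it became 0.241 for cartilage matrix, 0.05 for fibroblast-type collagens, 0.127 for hypertrophy and for p53 targets, and 0.169 for glycosaminoglycan synthesis, Wnt ligands and receptors, glycolysis, NRF2 targets, mitochondrial transcripts and macrophage markers. For both against control it became 0.128 for cartilage matrix, glycosaminoglycan synthesis and prostaglandin genes, 0.0723 for Wnt antagonists, 0.19 for NRF2 targets and 0.0793 for adipocyte markers.

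Fry, which by construction asks whether a list's genes move 1 way and does not compare them with other genes, called further lists. For IL-1β against control its adjusted p was 2.24e-09 for proteases, 2.51e-05 for protease inhibitors, 1.3e-07 for Wnt ligands and receptors, 6.27e-06 for interferon-stimulated genes, 0.0253 for TGF-β and BMP, 2.73e-06 for immediate early genes, 0.000312 for mitochondrial transcripts, and 1.23e-07, 0.000182, 3.41e-05, 1.18e-05 and 6.88e-08 for markers of macrophages, endothelium, muscle, osteoblasts and synovial fibroblasts. It was 1.41e-06 for Wnt/β-catenin targets and 0.000116 for hypertrophy, both up where camera's direction was down. With SFRP5 added it was 0.000936 for proteases, 0.000134 for inhibitors, 0.000145 for prostaglandin genes, 0.00126 for acute phase, 0.000289 for Wnt antagonists, 0.00183 for Wnt/β-catenin targets, 0.00625 for the unfolded protein response, 0.00148 for TGF-β and BMP and 0.00269 for muscle markers. For both against control it was 4.66e-09 for proteases, 7.8e-07 for inhibitors, 6.63e-07 for Wnt ligands and receptors, 1.27e-05 for fibroblast-type collagens, 6.33e-06 for immediate early genes, 8.37e-06 for mitochondrial transcripts, and 5.75e-07, 0.000701, 0.00747, 2.62e-05 and 4.87e-08 for markers of macrophages, endothelium, muscle, osteoblasts and synovial fibroblasts, and it was 1.13e-05 for Wnt/β-catenin targets, 3.6e-08 for hypertrophy and 0.024 for TGF-β and BMP, these 3 up where camera's direction was down. The cause of these differences in direction was not tested.

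Leaving out 1 library in turn moved the adjusted p across the threshold in 10 cases, each a list in 1 comparison. It ranged from 0.0116 to 0.0594 for osteoblast markers with IL-1β and from 0.0325 to 0.0867 for both against control. With SFRP5 added it ranged from 0.0459 to 0.133 for prostaglandin genes, 0.0211 to 0.0693 for Wnt ligands and receptors, 0.0274 to 0.137 for the unfolded protein response, 0.0153 to 0.0501 for p53 targets, 0.0108 to 0.263 for immediate early genes, 0.0123 to 0.0569 for mitochondrial transcripts, 0.0211 to 0.11 for macrophage markers and 0.0478 to 0.0958 for muscle markers. Fewer libraries lower the power of a test by construction, which can end calls. It does not account for calls gained, as with the osteoblast, prostaglandin, unfolded protein, immediate early and muscle lists. Their cause was not tested. On simulated counts with 50 genes changed 1.2-fold the test found 26% of them for IL-1β against control, 20% for SFRP5 added and 32% for both against control, but with so few changed genes the threshold is stricter than in the real data, where changes of this size were called.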

Other observations

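The families and genes in the next 2 paragraphs, except for Adamts5, Ptx3, Cxcl14 and Sox6, which the fixed rule names, the tests of mixing, uniform reduction, scaling and NRF2 targets, and the second test of Gapdh were chosen only after the results were seen, whereas the counts over other splits of the libraries and the first test of Gapdh were planned.

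SFRP5 left some genes beyond both other groups. Adamts5 was at 58.67 CPM in control, 64.84 with IL-1β and 146.1 with SFRP5 added, and Npas2, a partner of the clock protein BMAL1, at 2.78, 3.98 and 11.91 CPM. Cebpd, a transcription factor of the acute phase response, went from 10.6 to 80.92 and 194.5 CPM, the pantetheinase Vnn1 from 4.19 to 100.1 and 266.0 CPM, Ptx3 from 204.4 to 373.3 and 827 CPM, and Tnfaip6, which encodes the hyaluronan-binding protein TSG-6, from 3.22 to 8.27 and 18.93 CPM. These 4 rose with IL-1β and were higher still with SFRP5 added. In all, 43 genes moved in the same direction in both comparisons with at least a 2-fold change against IL-1β alone. As no group received SFRP5 alone, a change independent of IL-1β cannot be told from one in the response to it. Other genes passed control. Cxcl14 fell from 10.78 to 2.13 CPM with IL-1β and was at 17.14 CPM with SFRP5, the kinase Sgk1 went from 93.78 to 57.53 and 145.5 CPM, and Cemip, which takes part in hyaluronan breakdown, rose from 32.14 to 69.76 and was at 24.81 CPM with SFRP5. Fjx1 and Melk fell with IL-1β, from 9.96 to 4.22 and from 10.74 to 5.78 CPM, and fell further to 1.18 and 2.2 CPM with SFRP5.

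After a screen of 238 gene families, each sharing the text of the symbol before its first digit, 5 families were looked at. The proteasome and ribosomal families each join several such beginnings. Adjusting over the screen does not cover this joining. Proteasome subunits fell with SFRP5 in 23 of 38 cases and rose in 0 (median −0.17, and −0.15 to −0.18 under the other scalings, camera adjusted over the screen p = 2.49e-05), a call lost with an estimated correlation (adjusted p = 0.729). The family was not called with IL-1β, with 17 higher and 15 lower (median −0.03, adjusted p = 0.751). Psmd11 went from 64.9 in control to 164 and 106.9 CPM and Psmd14 from 62.1 to 101.9 and 71.52 CPM, whereas Psma5, at 43.62, 40.48 and 39.08 CPM, was called neither with IL-1β (adjusted p = 0.139) nor with SFRP5 added (adjusted p = 0.63). Subunits of the CCT chaperonin, which folds actin and tubulin, fell in 7 of 8 cases (median −0.25, adjusted p = 0.0209, and adjusted p = 0.729 with an estimated correlation), with Cct8 at 181.7, 302.8 and 234.7 CPM. SOX transcription factors fell with IL-1β in 8 of 9 cases (median −1.50, adjusted p = 0.0245, and adjusted p = 0.75 with an estimated correlation) and rose with SFRP5 in 5 (median 0.49, adjusted p = 0.0317, and adjusted p = 0.729 with an estimated correlation). Against control the family still had 7 of 9 lower with both treatments (median −1.48, adjusted p = 0.0765). Sox5, a partner of Sox9, went from 56.37 to 32.84 and 59.25 CPM, and Sox6 from 183.6 to 20.04 and 49.77 CPM. Genes of intraflagellar transport, which builds cilia, fell with IL-1β in 11 of 14 cases and rose with SFRP5 in 5, and ribosomal protein genes rose with SFRP5 in 34 and fell in 5 of 98 cases, but neither family passed the screen (adjusted p = 0.123, 0.318 and 0.18), and 45 of the 98 share over 20% of their windows with other genes.

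The first pattern is that genes moved by IL-1β lay closer to control with SFRP5. A candidate explanation is that control RNA or unstimulated cells were mixed into the SFRP5 libraries. With mixing alone, 1 share of control counts would account for nearly all genes that IL-1β lowered at least 32-fold. Of 66 such genes 75.8% departed from the median share of 1.81%. This percentage may be too high, as it rests on the SE, which is too small for such large changes. Mixing together with gene-specific changes would also give departures, so this test alone cannot set mixing aside. A mixed-in share of control counts would move lowered and raised genes by the same share. Yet 119 genes raised at least 32-fold had a median share of 27.7%, with 10th and 90th percentiles of −5.39 and 71.4%. For the 66 lowered genes these percentiles were 0.25 and 5.58%. The values argue against mixing as the main source of the fall in such raised genes. A reduction of the whole response by 1 factor was departed from by 33.9% of 6154 genes, and under RLE or upper-quartile factors at least 80.4% of the genes called in both comparisons still moved in opposite directions. Of 100 splits drawn from 840, 2 gave 3550 genes or more in opposite directions, the real one with its 3550 among them. The other, with 10305, had the 3 control libraries as its shared group, which points to the distance of control from both treated groups. Splits that mix control and treated libraries within a group inflate the spread. The median of 0 genes over the splits other than the real one follows largely from this, so its rank is weak evidence. A gene-specific effect of SFRP5 on the response remains a hypothesis. Mixing of a small share stays open. So does a lower effective dose of IL-1β to which genes respond unequally, as no dose series is part of the design. With no group given SFRP5 alone, an effect of SFRP5 independent of IL-1β stays open too.

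The second pattern is that antioxidant and NRF2 target genes moved back further than other genes raised by IL-1β. The list holds antioxidant genes beside NRF2 targets, and the 2 kinds were not tested apart. The median share undone was 29.2% over 15 members raised at least 2-fold, against 7.94% over 2845 other such genes, and 0.05% of 10000 random sets of as many genes reached it, with an adjusted p of 0.0108 over 18 lists. The next smallest adjusted p, 0.11, was that of NF-κB genes with 19.4% and of Wnt/β-catenin targets with 27.7%. The members of a list vary together, which random sets do not copy, so this p may be too small. The call of the list itself was lost with an estimated correlation (adjusted p = 0.169), and neither a mechanism nor a technical explanation was tested for it.

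The third pattern is that Gapdh, an enzyme of glycolysis often used as a reference gene, had 281, 397 and 296 counts in control, 6830, 1018 and 8276 with IL-1β and 6767, 3546 and 2807 with SFRP5. Its coefficient of variation within a group reached 70.3%, where the common value of all genes was 4.97%. A first test for reads split between near-identical copies was void, as Gapdh was the only gene left in its sum (70.3%). Summed over 71 genes, Gapdh and those with counts that share any window with it, the variation still reached 51%. The fall from 70.3% came mainly from a higher mean with IL-1β, 421.7 in place of 315.9 CPM. The SD there moved only from 222 to 215 CPM, so a split among these genes accounts for little of the variation. Copies missing from the annotation used here remain a candidate explanation. Biology was not tested, as no group of the design separates these libraries.

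With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Every split other than the real one mixes libraries of both groups on each side. Where many genes differ between the groups, this inflates the estimated spread. Few or no gene calls in these splits are thus nearly fixed in advance, and the ranking of gene counts carries little weight. The real splits, in fits of the 6 libraries compared, gave 12077, 4509 and 11700 genes for the 3 comparisons and ranked first (1 of 10 each), and the highest other split gave 0 in each in edgeR's test, or 30, 326 and 45 genes at an unadjusted p under 0.05. For lists the real splits gave 13, 16 and 12 calls, and the highest others 13, 5 and 11 (2, 1 and 1 of 10 as large). The lowest others gave 7, 1 and 8. In the 2 comparisons with control, the number of list calls thus barely set the real split apart. Why camera called lists in mixed splits was not tested. DESeq2 was not run on these splits.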
